A study of Homo sapiens with 8 samples.

How the data were processed

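RNA from Hep3B cells was hybridised to 8 one-colour (Cy3) Agilent SurePrint G3 arrays, all on 1 slide, with 1 array for each combination of 4 siRNAs and 2 adenoviruses. Per the labels, cells were infected at 100 moi 4 hours after a first siRNA transfection, transfected again 24 hours after infection and harvested 24 hours later, and 100 ng of RNA was labelled. The slide row follows the infection and the slide column follows the siRNA, so position on the slide and group cannot be told apart.

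The intensity values are, per the file headers, spot signals from Agilent Feature Extraction 10.7.3.1, background-subtracted and detrended per spot, with small or negative values replaced by a surrogate and nothing done between arrays. The raw mean and background intensities used in 1 alternative are also as deposited, before background subtraction. The other columns used are flags of 0 or 1 per spot, set by the software per the file headers, for signal well above background, non-uniform spots, outlier spots and saturation. The authors also deposited log2 values, for which their notes name Feature Extraction 10.7 and limma without a version or a method. Those log2 values correlated at 0.998 to 0.9996 with the log2 median signal of the same array, their sorted columns differed by at most 0.185, and they were not centred per gene. Every array had 58717 spots that were not controls, standing for 42405 probes, and 0 saturated spots. There were 34085 probes with 1 spot, 7321 with 2 spots and 999 with 10 spots. Probe coordinates are hg19, per the file headers. The number of arrays limits the precision.

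Processed signals were taken as log2 and the 75th percentile of the same array was subtracted. Spots marked as non-uniform or outliers were removed and the remaining spots of a probe were averaged. The plan drawn up before the data were examined describes this choice as leaving out probes with such a mark on any array. That reading would remove 961 probes, 909 of them among those with 10 spots, so single spots were removed instead and the wider removal was run as an alternative; 32 probes had no unmarked spot on some array and were left out. Probes well above background on at least 2 of the 8 arrays were tested. Probes were named through their RefSeq accession where possible (24826 probes), and each gene was counted by its brightest tested probe. A level in the text is log2 signal minus the array's 75th percentile, and a log2 difference is Ad-p53 minus Ad-LacZ, or lincRNA siRNA minus siControl.

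Groups were compared in limma 3.58.1 under R 4.3.3 (with version 1.17.8 of data.table, jsonlite 2.0.0, Matrix 1.6.5 and, for figures, matplotlib 3.10.9), with lmFit and eBayes with an intensity trend. The model held infection and siRNA, with 3 residual degrees of freedom and 3.57 from the prior, tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over 25392 probes with a threshold of 0.05. The residual spread includes any dependence of the p53 response on the siRNA. Comparisons of 1 array with 1 array are given as values without a test. Where no array of a group had a probe well above background, the fold is given as a bound, "at least N-fold". For it, the dim group's level on each array was raised to the lowest level called well above background on that array wherever it lay lower. Where no dim level lay lower, the fold is the fitted one and is given as such. The bounds hold only for the main processing and the probe used. Some probes at higher levels were also not well above background, so the bounds are not strict limits. For some genes other probes or alternatives, normexp among them, gave smaller differences. Where both groups had such arrays but only some of a group were well above background, their number is given. The difference is then a fitted value without an exact size.

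Gene lists were fixed before the data were examined: p53 targets in cell cycle and p53 feedback, in apoptosis and cell death, and in DNA repair and metabolism, G2 and mitosis, DNA replication, interferon response, NF-kB and inflammatory, hepatocyte, unfolded protein and amino acid stress, cholesterol synthesis, and glycolysis and hypoxia genes, and stromal and blood cell markers. They were tested with limma's camera at a preset inter-gene correlation of 0.01, beside an estimated correlation and fry, adjusted over 12 lists for infection and 36 list and siRNA combinations. None of the list calls passed with an estimated correlation. With fry, which asks whether a list's genes move one way on balance, the infection adjusted p-values were 0.00097 for the 3 p53 target lists and cholesterol synthesis genes 0.0057 for hepatocyte genes, 0.026 for NF-kB genes, 0.034 for G2 and mitosis genes and 0.14 for DNA replication genes, the last of which did not pass. Stromal and blood cell markers, not called by camera, had 0.043. Of the lists called by camera under an siRNA, only cholesterol synthesis genes with siTCONS_00022563 passed fry (adjusted p = 0.0198). With that siRNA the others had 0.0705 (hepatocyte and NF-kB genes), 0.65 (G2 and mitosis genes) and 0.68 (apoptosis targets), and with siTCONS_00020760 they had 0.21 (hepatocyte genes), 0.0705 (glycolysis and hypoxia genes) and 0.80 (G2 and mitosis genes). List medians of the p53 response were ranked among 10000 random lists of the same size matched on mean expression.

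Genes were named by a rule fixed before the data were examined. It takes the 10 largest increases and decreases under infection with the same sign in all 4 pairs, and the 5 largest each way per siRNA with the same sign under both infections. It adds the 3 members of each list with the smallest p in its main direction and 1 in the other direction if called. It further adds the 2 members with the smallest p of each list called under an siRNA, and for the p53 response the 3 targets furthest below and 1 furthest above siControl. CDKN1A, MDM2, BAX and the targeted lincRNAs were always included. Items named outside this rule are said to have been chosen after their values were seen. Of the genes taken by the rule, 1 is not named, because levels of XIST and Y-linked genes are not reported, and 2 more are not reported here, for a reason unrelated to their values.

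The alternatives were normexp background correction with an offset of 50, quantile normalization, the authors' processed values, no filter on dim probes, only probes well above background on all 8 arrays, marked spots kept, eBayes without a trend, robust eBayes, models without the siRNA or infection term, only the 4 arrays of an siRNA and siControl, the mean over a gene's probes, and leaving out each pair or array. Removal of whole probes with a marked spot, and of the Ad-p53 siTCONS_00022563 array alone for the infection comparison, were added after seeing the data. A slide block could not be fitted with 1 slide, and no probe carried a TCONS or XLOC identifier, so the targeted lincRNAs have no values.

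The procedure was tested on simulated data with 200 of 20817 genes changed. Of genes changed by 1 log2 unit it recovered 68.7% for infection and 14.9%, 23.9% and 35.8% for siTCONS_00004057, siTCONS_00020760 and siTCONS_00022563. Of genes changed by 2 log2 units it recovered 89.4%, 77.3%, 77.3% and 80.3%, with 3, 6, 3 and 2 false calls. A list shifted by 0.5 was called, and 0 of 11 other lists were. The simulated genes varied independently, whereas the correlation estimated on the real arrays was above the preset 0.01 for most lists. The simulation therefore does not show how often camera calls unchanged lists whose members move together.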

Results

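Gene expression was measured on 8 one-colour arrays of Hep3B cells, an established hepatocellular carcinoma line that lacks functional p53. The cells had received 1 of 4 siRNAs and 1 of 2 adenoviruses. Of the siRNAs, 3 were directed against the long intergenic non-coding RNAs (lincRNAs) TCONS_00004057, TCONS_00020760 and TCONS_00022563, and the remaining one, siControl, was a negative control. Ad-p53 carries the tumour suppressor p53, and Ad-LacZ carries a bacterial reporter and served as the infection control. Each of the 8 combinations of siRNA and virus was measured on 1 array, so each infection had 4 arrays and each siRNA had 2. The signal at the 75th percentile of an array lay between 664.84, on the Ad-p53 array of siTCONS_00022563, and 1000, on the Ad-LacZ array of siTCONS_00020760. Between 55.8% and 62.3% of the spots on an array were well above background. A total of 25392 probes, standing for 20817 genes or lincRNA regions, were tested. Nothing in the labels said that the arrays came from separate cultures, so the p-values measure the spread between these arrays, which may be technical, and the number of arrays limits their precision.

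The first question was how p53 changed gene expression in these cells. CDKN1A, the cyclin-dependent kinase inhibitor p21, rose by 6.41 ± 0.18 on the log2 scale (SE, 4 arrays per infection), although it was well above background on only 2 of the 4 Ad-LacZ arrays. Its smallest difference among the alternatives was 4.54. MDM2, the ubiquitin ligase that targets p53 for degradation, rose by 4.21 ± 0.34, and its other probes gave 3.34 and 3.94. BAX, which permeabilises the mitochondrial outer membrane, rose by 1.54 ± 0.07, from a mean of 3.41 to 4.96 log2 units above the 75th percentile. The limma adjusted p-values of these 3 genes lay between 8.2e-06 (CDKN1A) and 0.00041 (MDM2), and each was higher in 4 of 4 siRNA pairs. Their probes lie in hg19 at 36652178 to 36652237 on chromosome 6 (CDKN1A), 69238891 to 69238950 on chromosome 12 (MDM2) and 49464904 to 49464963 on chromosome 19 (BAX).

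**Figure D1:**
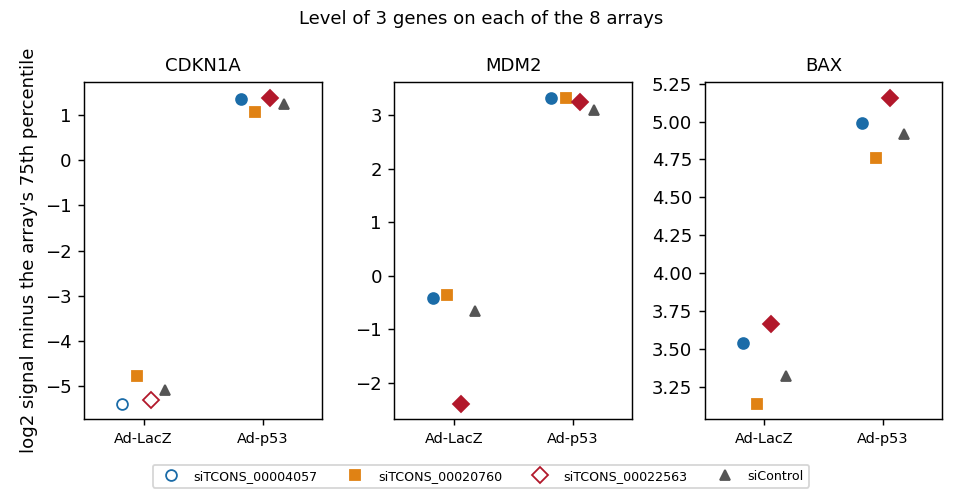
Level of CDKN1A, MDM2 and BAX on each array (vertical axis, log2 signal minus the array's 75th percentile; 1 point per array, open where the probe was not well above background), by infection on the horizontal axis and siRNA by symbol. All 3 genes sit higher on every Ad-p53 array than on every Ad-LacZ array.

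Across all genes, 8115 passed adjusted p under 0.05 between Ad-p53 and Ad-LacZ in limma, 3788 higher and 4327 lower under Ad-p53. The balance turned in 6 settings, with 3443 higher and 3138 lower without an intensity trend, 3549 and 3523 with no filter on dim probes, 2894 and 2271 without an siRNA term, and 1872 and 730, 3031 and 2351, and 3228 and 2824 without the siControl, siTCONS_00004057 and siTCONS_00020760 pairs; with quantile normalization it was 3328 and 5002. Changes of at least 2-fold were mostly increases, with 2368 genes higher and 709 lower. The largest increases were in genes that were not well above background on any Ad-LacZ array. LCN15, a lipocalin (hg19 chromosome 9, probe at 139654086 to 139654145), was 1748-fold higher under Ad-p53 as fitted (adjusted p = 4.2e-06). PHLDA3, a repressor of AKT signalling, was 468-fold higher as fitted. The smallest log2 differences of LCN15 and PHLDA3 among the alternatives were 8.67 and 6.75. The adhesion protein NECTIN4 (PVRL4 in the files) was at least 661-fold higher, the transcription factor OVOL1 at least 443-fold and KLHL30 at least 368-fold. SULF2, an extracellular heparan sulfate sulfatase, was at least 275-fold higher, the polo-like kinase gene PLK5P at least 251-fold and MGC50722 at least 243-fold. These bounds hold for the main processing only. Among the alternatives the smallest log2 differences were 7.02 for NECTIN4, 6.11 for OVOL1 and 5.85 for KLHL30. They were 5.73 for SULF2, 5.46 for PLK5P and 5.31 for MGC50722. FLJ36000 and the potassium channel gene KCNJ12, each well above background on 1 of 4 Ad-LacZ arrays, had fitted log2 differences of 9.32 ± 1.12 and 8.996 ± 0.592, which have no exact size; they were 6.5 and 5.94 with normexp, and the other FLJ36000 probes gave 4.20 and 4.31. The 5 largest increases among probes well above background on all 8 arrays, a selection made after the values were seen, were INPP5D (log2 difference 7.26 ± 0.15), BLNK (7.18 ± 0.24), CSH1 (7.14 ± 0.39, other probes 3.48 and 3.85), LAMP3 (6.73 ± 0.25) and APC2 (6.68 ± 0.33). INPP5D encodes a lipid phosphatase, BLNK a B cell adaptor, CSH1 a placental lactogen and LAMP3 a lysosomal membrane protein.

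The largest decreases were smaller in size. The liver-enriched transcription factor CREB3L3 fell by 2.50 ± 0.41 on the log2 scale (adjusted p = 0.0066) and was lower in 4 of 4 pairs. ABCG8, a subunit of a sterol transporter, was at least 5.65-fold lower, the sugar transporter gene SLC5A9 at least 4.78-fold, the sphingosine-1-phosphate receptor S1PR1 at least 3.69-fold and the nucleotide-sugar receptor P2RY14 at least 3.64-fold, none of them well above background on any Ad-p53 array. S1PR1 and P2RY14 were well above background on 3 and 2 of the 4 Ad-LacZ arrays, so their bounds rest in part on dim levels. Among the alternatives the smallest log2 differences of SLC5A9, S1PR1 and P2RY14 were -0.64, -0.54 and -0.52. KRT222 (log2 difference -2.44 ± 0.44), LRRC3 (-2.39 ± 0.43) and the protocadherin PCDH20 (-2.36 ± 0.39) fell as well, with 2, 2 and 1 of the 4 Ad-p53 arrays well above background. Their smallest differences among the alternatives were -0.87, -0.98 and -0.83. The pseudogene SEPTIN7P11 (LOC441601 in the files), well above background on 3 of the 4 Ad-LacZ arrays, was at least 6.53-fold lower (adjusted p = 0.037). Its call ended in 4 of 9 alternatives (adjusted p up to 0.19) and without the siTCONS_00020760 pair (adjusted p = 0.059), the siTCONS_00022563 pair (0.077), the Ad-p53 siTCONS_00022563 array alone (0.074) or the siControl pair (0.10). Calls of KRT222 (adjusted p = 0.053), P2RY14 (0.051), LRRC3 (0.060) and PCDH20 (0.054) also ended without the siControl pair. The count of called genes was 2602 without the siControl pair, 5382 without the siTCONS_00004057 pair and 5165 without an siRNA term. Differences of genes dim on one side were smaller with normexp background correction, falling from 10.77 to 8.67 for LCN15 and from -2.79 to -0.74 for ABCG8.

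Known p53 target genes rose as groups under Ad-p53. Of 25 measured targets in cell cycle control and p53 feedback, 19 rose and 0 fell, with a median log2 difference of 1.89 (camera adjusted p = 1.0e-11; adjusted p = 0.24 with an estimated correlation). They included PHLDA3, CDKN1A and GADD45A, a growth arrest and DNA damage protein that rose by 2.42 ± 0.10. Of 21 measured targets in apoptosis and cell death, 20 rose and 0 fell, with a median of 2.05 (camera adjusted p = 1.5e-13; adjusted p = 0.24 with an estimated correlation). The death receptor FAS was at least 66.8-fold higher (other probes 4.61 and 6.04 on the log2 scale), LRDD (PIDD1), a death domain protein, rose by 3.76 ± 0.105, and BBC3, the BH3-only protein PUMA, rose by 2.34 ± 0.09. Of 31 measured targets in DNA repair and metabolism, 27 rose and 1 fell, with a median of 1.80 (camera adjusted p = 3.5e-15; adjusted p = 0.24 with an estimated correlation). DDB2, which recognises UV lesions, rose by 4.22 ± 0.09, the mitochondrial reductase FDXR by 4.76 ± 0.16 and the lipid transporter ABCA12 at least 266-fold, while ALDH4A1, a proline catabolism enzyme, fell by 0.80 ± 0.14. Among the alternatives the smallest log2 differences of FAS and ABCA12 were 3.61 and 5.62. Adjusted over the list alone, the counts of these 3 lists were the same.

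Genes of G2 and mitosis fell together. Of 40 measured members, 39 fell and 1 rose, with a median log2 difference of -1.21 (camera adjusted p = 9.3e-12; adjusted p = 0.43 with an estimated correlation, which was 0.83 for this list). The mitotic kinase NEK2 fell by 1.47 ± 0.19, cyclin B2 (CCNB2) fell by 1.13 ± 0.16 and the spindle protein DLGAP5 fell by 1.09 ± 0.15. PTTG1, the securin that restrains separase, rose by 0.54 ± 0.17 (adjusted p = 0.0485), a call that ended in 4 alternatives (adjusted p up to 0.11) and without the siTCONS_00004057 pair (0.067), the siTCONS_00020760 pair (0.0765) or the siControl pair (0.092). Of 41 measured DNA replication genes, 17 fell and 6 rose (22 and 8 adjusted over the list alone), with a median of -0.36 (camera adjusted p = 0.0492; adjusted p = 0.53 with an estimated correlation). The replication list's call ended without the siTCONS_00022563 pair (adjusted p = 0.063), its Ad-p53 array alone (0.063) or the siControl pair (0.061), and with quantile normalization (0.60), the authors' processed values (0.49) and only probes well above background on all arrays (0.20). The polymerase subunit POLE2 fell by 0.91 ± 0.15, the helicase subunit MCM6 fell by 0.49 ± 0.10 and the ribonucleotide reductase subunit RRM2 fell by 1.015 ± 0.20, whereas PCNA, the sliding clamp, rose by 1.61 ± 0.11. Without the siControl pair the adjusted p of MCM6 was 0.064 and that of RRM2 was 0.053. The fall of G2 and mitosis genes was largest in the siTCONS_00022563 pair, whose Ad-p53 array had the lowest 75th percentile signal of the 8, though not the lowest median signal.

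Hepatocyte and cholesterol synthesis genes were also lower. Of 37 measured hepatocyte genes, 24 fell and 1 rose, with a median of -0.50 (camera adjusted p = 1.4e-06; adjusted p = 0.27 with an estimated correlation). The plasma protein genes haptoglobin (HP), ITIH1 and fibrinogen gamma (FGG) fell, with log2 differences of -1.95 ± 0.16, -1.55 ± 0.15 and -1.39 ± 0.14, and complement C3 rose by 0.49 ± 0.07. Of 24 cholesterol synthesis genes, 20 fell and 1 rose (20 and 2 adjusted over the list alone), with a median of -0.61 (camera adjusted p = 3.1e-06; adjusted p = 0.24 with an estimated correlation). Mevalonate kinase (MVK) fell by 0.84 ± 0.08 and squalene epoxidase (SQLE) fell by 1.12 ± 0.13, while phosphomevalonate kinase (PMVK) rose by 0.47 ± 0.13. The PMVK call ended without the siTCONS_00020760 pair (adjusted p = 0.067) or the siControl pair (0.12). Calls of HP (adjusted p = 0.059), FGG (0.083) and PMVK (0.074) ended without an siRNA term.

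Of 20 measured NF-kB and inflammatory genes, 12 rose and 2 fell, with a median of 0.49 (camera adjusted p = 0.0033; adjusted p = 0.43 with an estimated correlation). NFKBIA, the inhibitor of NF-kB, rose by 0.73 ± 0.08, IER3 by 1.22 ± 0.15 and the NF-kB subunit RELB by 0.53 ± 0.08, and BCL3 fell by 0.55 ± 0.12. The RELB call ended without an siRNA term (adjusted p = 0.34) and the BCL3 call without the siControl pair (0.052). Interferon response genes did not pass as a list, with 6 of 25 measured members higher, 2 lower and a median of 0.30 (camera adjusted p = 0.072; adjusted p = 0.53 with an estimated correlation). Within it IFIT3 was at least 63.1-fold higher, ISG15 rose by 2.50 ± 0.31, OAS3 rose by 1.36 ± 0.175 and PARP9 fell by 0.84 ± 0.18. The smallest log2 differences of IFIT3, OAS3 and PARP9 among the alternatives were 3.76, 0.68 and -0.33. The PARP9 call ended without the siControl pair (adjusted p = 0.065) and without an siRNA term (0.11).

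The remaining lists did not pass the test. Unfolded protein and amino acid stress genes went both ways, with 7 of 28 higher and 9 lower (8 and 10 adjusted over the list alone) and a camera adjusted p of 0.96; their median was -0.04 and their mean 0.11. PHGDH, the first enzyme of serine synthesis, fell by 0.98 ± 0.09, XBP1 fell by 0.88 ± 0.12 and the cystine transporter SLC7A11 fell by 0.72 ± 0.12, while the stress transcription factor ATF3 rose by 2.26 ± 0.09 (other probes 0.63 to 2.58). Calls of PHGDH (adjusted p = 0.083) and SLC7A11 (0.055) ended without an siRNA term. Of 28 glycolysis and hypoxia genes, 10 fell and 6 rose, with a median of -0.20, a mean of 0.23 and a camera adjusted p of 0.37. The histone demethylase KDM3A fell by 0.92 ± 0.13, the aldolase ALDOC fell by 0.75 ± 0.12 and the prolyl hydroxylase subunit P4HA1 fell by 0.78 ± 0.15, whereas PFKP, a phosphofructokinase well above background on 3 of the 4 Ad-LacZ arrays, rose by 6.92 ± 0.17. Calls of ALDOC (adjusted p = 0.15) and P4HA1 (0.13) ended without an siRNA term, and that of P4HA1 without the siControl pair (0.069). Of the stromal and blood cell markers, 12 of 22 were measured, 6 were higher, 2 were lower and the median was 0.82 (camera adjusted p = 0.089). Collagen COL1A2, well above background on 2 of the 4 Ad-LacZ arrays, rose by 3.22 ± 0.33 (1.69 with normexp), the monocyte antigen CD14 by 2.28 ± 0.26, the endothelial VWF at least 6.87-fold, and the macrophage antigen CD68 fell by 0.86 ± 0.14. Among the alternatives the smallest log2 difference of VWF was 1.06. These markers were measured on the same arrays as the groups above.

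**Figure D2:**
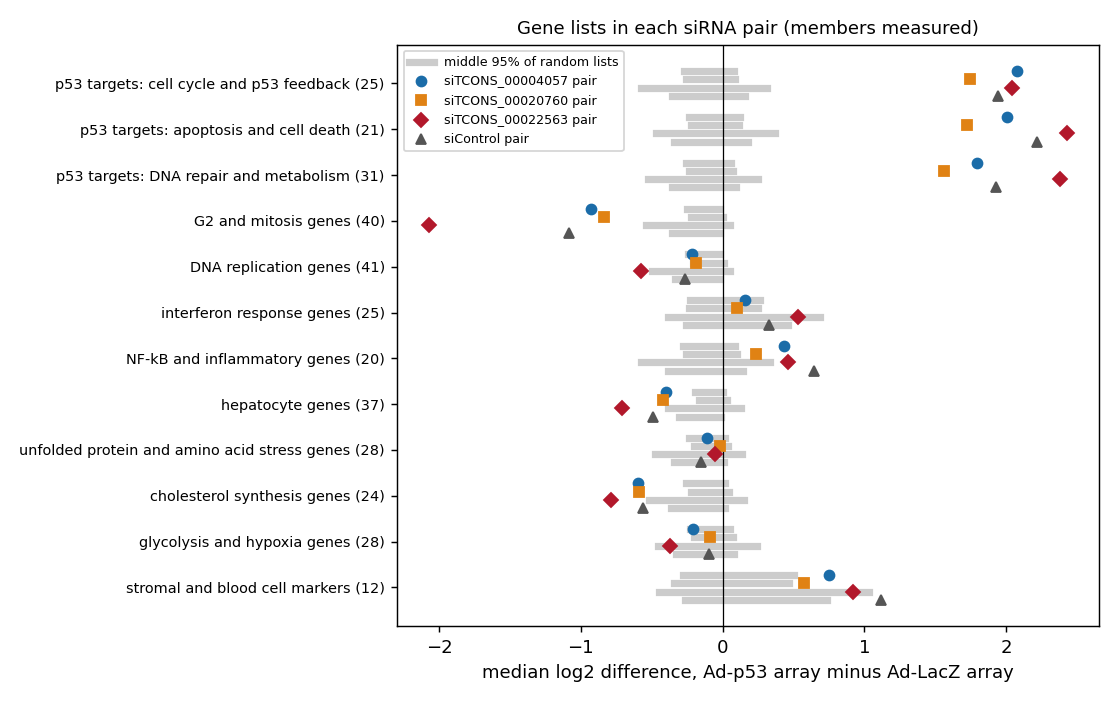
Median log2 difference between the Ad-p53 and Ad-LacZ arrays of the same siRNA (horizontal axis) for the 12 gene lists, 1 symbol per siRNA pair; grey bars span the middle 95% of 10000 random lists of the same size matched on mean expression. The 3 lists of p53 targets lie between 1.56 and 2.43 and G2 and mitosis genes between -2.07 and -0.84.

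The array also carried probes for lincRNA regions, which it names by hg19 position. Of 3291 tested regions, 403 were higher (12.3%) and 244 lower (7.41%) under Ad-p53, against 3385 (19.3%) and 4083 (23.3%) of 17526 other genes. The shares were not matched on signal, on which a call depends, and overlapping regions were counted separately. Whether lincRNA regions respond less than other genes was not tested. The region on the reverse strand of chromosome 21 from 45228747 to 45238991 was at least 136-fold higher, and that on the forward strand of chromosome 1 from 142840948 to 142842761 at least 54.5-fold higher. Reverse-strand regions were at least 32.1-fold higher on chromosome 6, from 48044816 to 48070216, and at least 20.7-fold higher on chromosome 4, from 82523980 to 82965397. The reverse-strand region on chromosome 8 from 87026584 to 87038559 was at least 4.20-fold lower (adjusted p = 0.028). These 5 regions were chosen after their values were seen.

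The next question was what each lincRNA siRNA did to gene expression. No probe carried a TCONS or XLOC identifier, so the targeted RNAs could not be matched and the knockdown could not be checked. Each siRNA was set against siControl over both infections, 2 arrays against 2, and an array left out changes the count of calls by more than 1.5 times in each of the 3 comparisons.

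With siTCONS_00004057, 60 genes were higher and 61 lower than with siControl in limma, all of them with the same sign under both infections. Opposite signs under the infections would widen the residual spread and keep a gene from being called. The shared sign of called genes therefore follows from the test and is no separate support, here and for the other siRNAs. SETD7, a lysine methyltransferase, rose by 2.44 ± 0.17 on the log2 scale (adjusted p = 0.016). The others were UBE2B, a ubiquitin-conjugating enzyme of post-replication repair, at 2.37 ± 0.25, NBN, a subunit of the MRE11 DNA break repair complex, at 2.37 ± 0.25, and UQCC6 (C12orf73 in the files) at 2.13 ± 0.16. NUMBL was at least 4.996-fold higher than on the siControl arrays, where it was not well above background (adjusted p = 0.041). MIXL1, a homeobox transcription factor, fell by 2.92 ± 0.41 and FAM174A fell by 2.43 ± 0.26. Log2 differences of the other decreases were -2.30 ± 0.25 for GBA3, a cytosolic beta-glucosidase, -2.27 ± 0.325 for the flavin monooxygenase FMO1 and -2.185 ± 0.23 for the actin-binding protein TAGLN (second probe -2.995). MIXL1 was well above background on 1 of the 2 arrays with this siRNA, as was CDKN1A. CDKN1A, MDM2 and BAX had log2 differences of -0.10 ± 0.25, 0.24 ± 0.48 and 0.15 ± 0.11, and none passed (lowest limma adjusted p = 0.60). The second BAX probe gave 0.44. No gene list passed camera, the lowest adjusted p being 0.099 for cholesterol synthesis genes with a median of 0.08; the apoptosis, glycolysis and stromal lists had medians just below 0 (-0.0089, -0.02 and -0.0047) and a test direction above it. Among lincRNA regions, 7 were higher and 1 lower, the latter on the forward strand of chromosome 2 from 162101249 to 162105559, which fell by 1.44 ± 0.19.

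The 121 calls fell to 0 without any 1 of 6 arrays, namely both siTCONS_00004057 arrays, both siTCONS_00020760 arrays and both siControl arrays, where between 1032 and 2444 genes had an unadjusted p under 0.05. They numbered 1210 without the Ad-p53 siTCONS_00022563 array and 1087 without its Ad-LacZ array. No call was left with eBayes without an intensity trend (2701 at an unadjusted p under 0.05) or without an infection term (1108). Of the 10 named genes, NUMBL, MIXL1, FAM174A, GBA3, FMO1 and TAGLN did not pass with normexp background correction (adjusted p between 0.0501 and 0.13), where NUMBL differed by 0.60 and MIXL1 by -0.95. With the authors' processed values NUMBL, NBN, MIXL1, FAM174A, GBA3 and FMO1 did not pass (adjusted p between 0.0536 and 0.102), nor did NUMBL, MIXL1 and FMO1 with no filter on dim probes (0.057 to 0.059) or NUMBL (0.052) and FMO1 (0.088) with quantile normalization. FMO1, with an adjusted p of 0.0497, was lost in 8 of 11 alternatives, also with marked spots kept (0.0506) and robust eBayes (0.0522).

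With siTCONS_00020760, 103 genes were higher and 115 lower than with siControl, again with the same sign under both infections, which follows from the test. TNPO1, a nuclear import receptor, rose by 2.57 ± 0.17 on the log2 scale (adjusted p = 0.014), the neuropeptide galanin (GAL) by 2.65 ± 0.29, the metallothionein MT1M by 2.72 ± 0.37 and the integrin subunit ITGA2 by 2.49 ± 0.37, MT1M and ITGA2 being well above background on 1 of the 2 siControl arrays. NUMBL was at least 5.11-fold higher. TMEM14A fell by 2.43 ± 0.20 and the chemokine CXCL10 fell by 2.39 ± 0.28. Log2 differences of the other decreases were -2.295 ± 0.30 for SPHAR, -2.18 ± 0.17 for CSGALNACT2, a chondroitin sulfate enzyme (second probe -1.42), and -2.16 ± 0.16 for PACRGL. CDKN1A, MDM2 and BAX had log2 differences of 0.07 ± 0.25, 0.27 ± 0.48 and -0.17 ± 0.11, and none passed (lowest limma adjusted p = 0.55). The second BAX probe gave 0.29 with this siRNA.

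Hepatocyte genes were lower as a list with siTCONS_00020760, with 3 of 37 members lower and 0 higher (8 lower adjusted over the list alone) and a median of -0.22 (camera adjusted p = 0.00059 over 36 tests; adjusted p = 0.90 with an estimated correlation). CPS1, the first enzyme of the urea cycle, fell by 1.51 ± 0.15 and transthyretin (TTR) fell by 0.86 ± 0.10. The list's adjusted p was 0.080 without the Ad-LacZ siTCONS_00020760 array. Glycolysis and hypoxia genes were higher as a list, with 1 of 28 members higher and a median of 0.14 (camera adjusted p = 0.030; adjusted p = 0.62 with an estimated correlation). That member was CA9, a hypoxia-induced carbonic anhydrase, at 2.42 ± 0.35; PKM (PKM2 in the files), a pyruvate kinase, differed by 0.61 ± 0.14 (adjusted p = 0.135) without passing. The list's adjusted p was 0.12 without the Ad-p53 siTCONS_00020760 array, 0.19 without the Ad-p53 siControl array and 0.072 with no filter on dim probes. G2 and mitosis genes were lower as a list with a median of -0.26, although 0 of 40 members passed (camera adjusted p = 0.030; adjusted p = 0.93 with an estimated correlation). CENPF and PRC1, which act at the kinetochore and the spindle midzone, differed by -1.36 ± 0.28 and -1.22 ± 0.30 (adjusted p = 0.11 and 0.15); CENPF, PRC1 and PKM passed without either siTCONS_00022563 array (adjusted p between 0.0059 and 0.040). The list's direction turned upward without the Ad-LacZ siTCONS_00020760 array (adjusted p = 0.98), and its call ended without the Ad-p53 siControl array (0.38), with normexp (0.12), with quantile normalization (0.0616) and with the authors' processed values (0.096).

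Of the lincRNA regions, 3 were lower and 15 higher with siTCONS_00020760. The reverse-strand region on chromosome 7 from 77287012 to 77290598 was at least 3.67-fold lower, the reverse-strand region on chromosome 6 from 30258570 to 30262400 fell by 1.08 ± 0.15 and a forward-strand region on chromosome 1 from 211556096 to 211605878 fell by 1.02 ± 0.15. The 218 calls fell to 0 without any 1 of the 6 arrays of siTCONS_00004057, siTCONS_00020760 and siControl, where between 1114 and 2486 genes had an unadjusted p under 0.05. They numbered 1405 without the Ad-p53 siTCONS_00022563 array and 1310 without its Ad-LacZ array, and 0 with eBayes without an intensity trend (2675 at an unadjusted p under 0.05) or without an infection term (1151). With normexp, NUMBL, ITGA2, SPHAR, TTR and CA9 had adjusted p-values between 0.051 and 0.16, and NUMBL, ITGA2 and CA9 differed by 0.64, 0.82 and 1.01. The smallest log2 differences of MT1M and CSGALNACT2 among the alternatives were 1.15 and -1.22. With the authors' processed values NUMBL, ITGA2, CXCL10, SPHAR, TTR and CA9 did not pass (adjusted p between 0.0565 and 0.0874), nor did ITGA2 (0.064) and CA9 (0.059) with no filter on dim probes or CA9 with quantile normalization (0.0545).

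With siTCONS_00022563, 156 genes were higher and 230 lower than with siControl, with the same sign under both infections, which follows from the test. GBA3 fell by 3.79 ± 0.25 on the log2 scale (adjusted p = 0.0041). Log2 differences of the other decreases were -2.91 ± 0.26 for ODAM, an odontogenic protein gene, -2.89 ± 0.27 for GSTA5, a glutathione transferase well above background on 1 of the 2 arrays with this siRNA, and -2.86 ± 0.16 for the estrogen sulfotransferase SULT1E1. GPX8, a glutathione peroxidase family member of the endoplasmic reticulum, was at least 3.77-fold lower. Keratin 14 (KRT14) rose by 2.77 ± 0.33, the adrenergic receptor ADRA2C by 2.57 ± 0.36, MDFIC by 2.51 ± 0.33, RPRM, a p53-induced mediator of G2 arrest, by 2.50 ± 0.32 and UQCC6 by 2.43 ± 0.16. KRT14 and RPRM were well above background on 1 of the 2 siControl arrays, and CDKN1A on 1 of the 2 arrays with this siRNA. CDKN1A, MDM2 and BAX had log2 differences of -0.04 ± 0.25, -0.80 ± 0.48 and 0.29 ± 0.11, and none passed (lowest limma adjusted p = 0.21). Without the Ad-p53 siTCONS_00022563 array MDM2 differed by -1.75, a value that rests on 1 Ad-LacZ array with this siRNA. On that Ad-LacZ array the other MDM2 probes differed from siControl by -0.577 and -0.375. Over both infections the other MDM2 probes gave -0.14 and -0.10, and the second BAX probe 0.59.

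Several lists moved with siTCONS_00022563. Cholesterol synthesis genes were lower, with 5 of 24 members lower and 0 higher (17 lower adjusted over the list alone) and a median of -0.55 (camera adjusted p = 3.2e-09; adjusted p = 0.38 with an estimated correlation). NSDHL, a sterol dehydrogenase, fell by 0.83 ± 0.11. Hepatocyte genes were lower, with 10 of 37 lower and 0 higher (18 and 1 adjusted over the list alone) and a median of -0.42 (camera adjusted p = 6.1e-09; adjusted p = 0.62 with an estimated correlation), including HP at -2.66 ± 0.23 and TTR at -1.67 ± 0.10. NF-kB and inflammatory genes were higher, with 5 of 20 higher and 0 lower (10 higher adjusted over the list alone) and a median of 0.66 (camera adjusted p = 3.8e-07; adjusted p = 0.62 with an estimated correlation). Lymphotoxin beta (LTB) rose by 2.055 ± 0.24 and the apoptosis inhibitor BIRC3 by 1.31 ± 0.15. G2 and mitosis genes were lower as a list with a median of -0.58 (camera adjusted p = 3.8e-06; adjusted p = 0.93 with an estimated correlation), although 0 of 40 members passed, NEK2 differing by -1.21 ± 0.26 (adjusted p = 0.082) and CENPF by -0.99 ± 0.28 (0.14). Their median was -1.07 under Ad-p53 and -0.11 under Ad-LacZ, and the list's adjusted p was 0.95 without the Ad-p53 siTCONS_00022563 array. Calls of NEK2 and CENPF without the Ad-LacZ array of this siRNA rest on 1 array and are not counted as support. The apoptosis targets of p53 were higher as a list with a median of 0.30 (camera adjusted p = 0.045, and 0.93 with an estimated correlation). Of its members 0 were called higher and 1 was called lower, and TNFAIP8 differed by 1.14 ± 0.33 (limma adjusted p = 0.14). PMAIP1 did not pass and was well above background on 1 of the 2 arrays of each group, so its difference has no exact size. That call ended in 6 of 7 alternatives (adjusted p up to 0.93) and without the Ad-p53 siTCONS_00022563 array (0.59), either siTCONS_00004057 array (0.056 each), the Ad-p53 siControl array (0.071) or the Ad-LacZ siControl array (0.15).

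**Figure D3:**
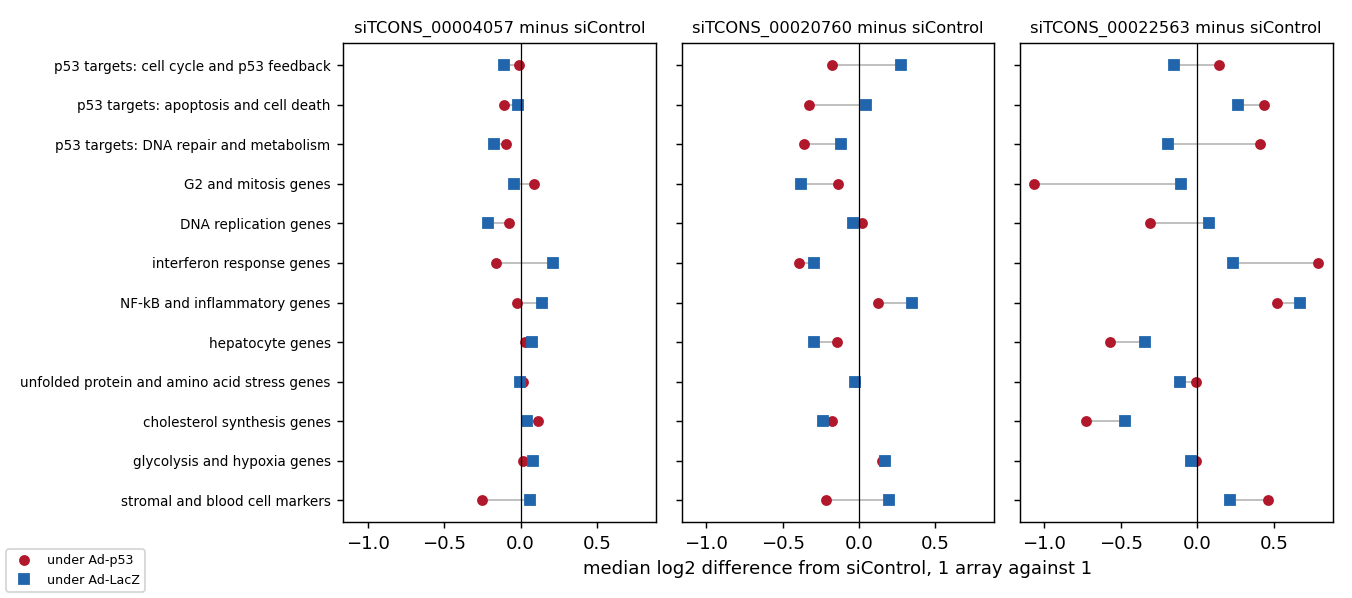
Median log2 difference of the 12 gene lists between each lincRNA siRNA and siControl (horizontal axis), with circles for the Ad-p53 arrays, squares for the Ad-LacZ arrays and a line joining both. For siTCONS_00022563, cholesterol synthesis genes lie at -0.73 and -0.48 and G2 and mitosis genes at -1.07 and -0.11.

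Of the lincRNA regions, 5 were lower and 11 higher with siTCONS_00022563. The reverse-strand region on chromosome 2 from 54284416 to 54307601 fell by 2.94 ± 0.17 and that on chromosome X from 71132475 to 71339425 fell by 2.19 ± 0.15. The other 3 lay on chromosome 6 from 34244122 to 34253847 (-1.68 ± 0.27), chromosome 7 from 139250476 to 139251206 (-1.20 ± 0.16) and chromosome 20 from 31438639 to 31447464 (-1.17 ± 0.14). The lincRNA regions named for the 3 siRNAs were chosen after their values were seen. The 386 calls numbered 0 without the Ad-LacZ siControl array (1729 at an unadjusted p under 0.05), 1 without the Ad-p53 siControl array, 77 and 71 without the Ad-p53 and Ad-LacZ siTCONS_00004057 arrays and 135 and 114 without those of siTCONS_00020760. They numbered 957 without the Ad-p53 siTCONS_00022563 array and 4829 without its Ad-LacZ array, 61 with eBayes without an intensity trend and 2 without an infection term. With normexp, KRT14 (1.37), RPRM (1.56), ODAM (-1.67), GSTA5 (-1.78), GPX8 (-0.67) and NSDHL (-0.79) did not pass, their adjusted p-values lying between 0.0507 and 0.23. KRT14, RPRM, GPX8, BIRC3 and NSDHL did not pass with the authors' processed values (0.061 to 0.17), and GPX8 (0.058), BIRC3 (0.067) and NSDHL (0.093) did not with only the 4 arrays of this siRNA and siControl. KRT14, ADRA2C, MDFIC, RPRM, GPX8, BIRC3, LTB and NSDHL were lost without an intensity trend (0.052 to 0.098) and without at least 1 of the siTCONS_00004057 arrays (0.0509 to 0.0947); GPX8, BIRC3 and NSDHL were also lost without either siTCONS_00020760 array (0.0502 to 0.0708).

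The 3 siRNA comparisons share the siControl arrays. With all 3 lincRNA siRNAs, 30 genes or lincRNA regions passed, 28 higher and 2 lower than with siControl, overlapping regions being counted separately. NUMBL, UQCC6, NBN, TNPO1, SETD7 and UBE2B were among the higher ones, and GBA3 and SULT1E1 were the lower ones. SULT1E1 differed by -1.39, -1.71 and -2.86 with siTCONS_00004057, siTCONS_00020760 and siTCONS_00022563. The genes higher in both members of a pair of comparisons numbered 36, 34 and 50 and those lower in both numbered 5, 4 and 12, and no gene passed in opposite directions; since the comparisons share arrays, no number expected by chance is given. Pearson correlations across genes were 0.51, 0.30 and 0.37, against 0.50 in simulations of unchanged groups that share controls. The covariances were 0.12, 0.080 and 0.096 against 0.053 simulated. The siControl arrays, 1 per infection, could not be divided between the comparisons. Between infections, which share no array, the difference from siControl correlated across genes at Pearson 0.42, 0.36 and 0.34 (Spearman 0.44, 0.39 and 0.32) for siTCONS_00004057, siTCONS_00020760 and siTCONS_00022563, and at 0.13 to 0.20 for different siRNAs. Genes are not independent replicates, and no p-value was computed for these correlations.

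The last question was whether the p53 response itself differed by siRNA. With 1 pair of arrays per siRNA, these differences have no replicate check and no test. All differences from siControl below use the same siControl pair, so a high value in that pair alone would lower the differences of all 3 lincRNA siRNAs. Among p53 targets, the log2 response of ASCC3, a helicase of DNA alkylation repair, was 3.21 with siControl, 1.20 with siTCONS_00004057, 0.77 with siTCONS_00020760 and 1.99 with siTCONS_00022563. CCNK responded by 0.97 with siTCONS_00004057 and 1.91 with siTCONS_00022563, against 2.48 with siControl. SFN, the 14-3-3 sigma protein of G2 arrest, responded by 5.89 with siTCONS_00004057 and 5.20 with siTCONS_00020760, against 7.35. Responses above siControl were those of SESN1 with siTCONS_00004057 (3.49 against 2.63) and DCP1B with siTCONS_00020760 (1.42 against 0.79). CASP1 with siTCONS_00020760, and CYFIP2 and PMAIP1, the BH3-only protein NOXA, with siTCONS_00022563 were also taken by the rule, but they were not well above background on 1 or both of the Ad-LacZ arrays compared, so their differences have no exact size or rank.

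As groups, G2 and mitosis genes had median responses of -0.93 with siTCONS_00004057, -0.84 with siTCONS_00020760, -2.07 with siTCONS_00022563 and -1.08 with siControl. Their difference from siControl was -0.94 with siTCONS_00022563, below all 10000 random lists of the same size matched on expression, and went the other way with siTCONS_00004057 (0.17, percentile 98.01) and siTCONS_00020760 (0.28, percentile 100). With siTCONS_00020760 the apoptosis targets differed from siControl by -0.46 (0.01 percentile of random lists), NF-kB genes by -0.38 (percentile 0) and cell cycle targets by -0.22 (percentile 0.09). With siTCONS_00022563 interferon response genes differed by 0.73 (percentile 100), NF-kB genes by -0.42 (percentile 0.18) and DNA repair and metabolism targets by 0.34 (percentile 99.9). The apoptosis targets (0.34, percentile 99.32) and cell cycle targets (0.31, percentile 99.33) were also above siControl in that pair. Hepatocyte genes were below it (-0.24, percentile 0.06). In all, 16 of 36 such differences lay outside the middle 95% of random lists, and 11 did with normexp and 11 with the authors' processed values. Random lists lack the correlation among a list's members, so these ranges are too narrow for lists whose members move together. They were matched on expression and not on size of response. A list that responds strongly can therefore leave them when all responses of a pair are smaller or larger. Fitted to genes outside the G2 and mitosis list, slopes on siControl's responses were 0.747 with siTCONS_00004057, 0.719 with siTCONS_00020760 and 1.15 with siTCONS_00022563. G2 and mitosis genes lay -0.113, -0.0419 and -0.793 from these lines, in that order. The other lists were not set against these lines. Their percentiles therefore do not tell a change of the list itself from smaller or larger responses of the whole pair. Under a principal component analysis, the first component held 72.1% of the variance and separated the infections, with the Ad-p53 siTCONS_00022563 array at -140.6 and the other Ad-p53 arrays between -73.9 and -51.9.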

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

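All tests of explanations in this part, including the splits of the arrays and the search for short words in probe sequences, were chosen only after the results were seen. The model pairs the arrays by siRNA, and 8 splits of the arrays into 4 and 4 part each pair, too few for a share under 0.05. The real split called 8115 genes between infections and the highest other called 0, so 1 of the 8 called as many. Every other split leaves all or part of the infection difference in the residual spread. Their 0 calls were therefore likely beforehand and do not show what chance gives. The real split called 8 gene lists and the highest other called 9, with 3 of the 8 calling as many. The other splits that called as many did not balance the infections, so part of the infection difference entered the comparison. Splits that balanced them called 3, 1 and 2 lists. The tally therefore does not show how many lists a grouping without an infection difference calls.

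In the siTCONS_00022563 pair, 4 of the 82 sets of 4 pair responses tested had a value far from the other 3; no set did in another pair, and chance gives about 1 in 20 over all 4 pairs together. CCNB2 responded by -1.75 against -0.98 to -0.85 in the other pairs, and PARP9 by -1.45 against -0.70 to -0.54. MDM2 responded by 5.64 against 3.685 to 3.76, while its other probes gave smaller gaps, 4.79 against 3.49 to 3.91 and 3.8 against 3.02 to 3.27. The median response of cholesterol synthesis genes was -0.787 against -0.60 to -0.56.

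Among CDKN1A, MDM2 and BAX, differences from siControl had opposite signs under Ad-p53 and Ad-LacZ for 4 combinations of gene and siRNA. Each infection had 1 array per siRNA, and these differences between infections were not tested. CDKN1A differed by -0.162 under Ad-p53 and 0.30 under Ad-LacZ with siTCONS_00020760. With siTCONS_00004057 and siTCONS_00022563 it differed by 0.105 and 0.146 under Ad-p53 and was not well above background on the Ad-LacZ arrays of these siRNAs, so its negative differences under Ad-LacZ have no exact size. MDM2 with siTCONS_00022563 differed by 0.142 and -1.73, and its other probes by 0.303 and -0.577 and by 0.168 and -0.375.

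The fall of G2 and mitosis genes under Ad-p53 was 0.94 log2 units larger in the siTCONS_00022563 pair than in the siControl pair (median difference -0.94), and the Ad-p53 array of that pair had the lowest signal at the 75th percentile, by which arrays were scaled, though not the lowest median. Array brightness and scaling as the cause are argued against by quantile normalization, after which the difference was -1.03. A wider response of all genes cannot be told apart: the line fitted to the other genes had a slope of 1.15, and the list lay -0.793 from it, outside the range of -0.226 to 0.109 for random lists. Those lists lack the correlation among its members, estimated at 0.83, so they do not show how far such a list moves by chance on 1 array. A stronger infection on that array was not tested, and with 1 array it cannot be told apart from the effect of the siRNA. An effect of the targeted lincRNA on the p53 response, which the design names, also stays open and untested.

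With the lincRNA siRNAs, 28 genes or lincRNA regions, overlapping regions being counted separately, were higher than with siControl in all 3 comparisons. Chance values of the shared siControl arrays cannot be told apart from an effect. Differences of different siRNAs, one taken under Ad-p53 and the other under Ad-LacZ, had a mean covariance of 0.0633 across all genes (0.0484 to 0.0847 over 6 combinations). With each lincRNA siRNA as the reference instead it was 0.0505 to 0.0829, and 4 references are too few to set siControl apart. An effect of siControl itself, or one common to the lincRNA siRNAs, could give the same values and stays open. Slide column cannot be told apart from siRNA, since 0 columns held more than 1 siRNA. The word of 7 bases whose probes were highest under Ad-LacZ, CATCTAC, differed by 0.00895 under Ad-p53 (permutation p = 0.78, adjusted p = 1), which decides nothing, and 0 of the 28 probes held it.

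A short match between an siRNA and other transcripts is a candidate explanation for part of the genes lower with single siRNAs. Probes with the word TCTGTCA, chosen under Ad-LacZ from 11358 words, were lower with siTCONS_00004057 under Ad-p53 too, by a mean difference of -0.19 over 139 probes (79.1% lower against 58.2% of the others), and probes with AGCACTA were lower with siTCONS_00020760 by -0.468 over 55 probes (81.8% against 58.7%). Differences of an siRNA agree between infections, so a word chosen under Ad-LacZ is expected to be lower again; probe sequences were therefore shuffled and the word chosen anew each time. Both words had a permutation p of 5e-04, the smallest that 2000 permutations can give (adjusted p = 0.001). Of 611 rearrangements of the same bases 0 had an effect as large, but these were not chosen as extremes, so that count alone decides nothing. The part beyond their mean, set against words chosen anew, had the same p, which argues against base composition. The shuffling treats probes as independent. For siTCONS_00022563 the word GTGTGTG differed by 0.228 under Ad-p53, opposite to Ad-LacZ (one-sided permutation p = 1), which argues against that word, and no other word was tested. The siRNA sequences were not in the sources used here, so no word could be linked to an siRNA, and loss of the targeted lincRNA stays open as a biological cause.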

How the results depend on the processing

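Alternatives that leave out whole probes with a marked spot, or the Ad-p53 siTCONS_00022563 array alone under infection, were chosen after the data were seen. The infection count stayed within 1.5 times of 8115 in 9 of 10 alternatives (6581 to 8330); it was 5165 without an siRNA term, and leaving out a pair or array gave 2602 (without the siControl pair) to 7853. The siTCONS_00004057 count of 121 was 46 with normexp, 41 with the authors' values, 196 with only probes well above background on all 8 arrays, 682 with only the 4 arrays of this siRNA and siControl, and 0 in limma without a trend (2701 at an unadjusted p under 0.05) or without an infection term (1108); arrays left out in turn gave 0 to 1210. The siTCONS_00020760 count of 218 was 89 with normexp, 56 with the authors' values, 1042 with 4 arrays, and 0 without a trend (2675 unadjusted) or an infection term (1151); arrays left out gave 0 to 1405. The siTCONS_00022563 count of 386 was 185 with normexp, 178 with the authors' values, 61 without a trend, 2 without an infection term and 177 with 4 arrays; arrays left out gave 0 to 4829. The cause of these moves was not tested. With an estimated correlation 0 lists were called in both families, and otherwise 7 or 8 under infection and 6 to 10 under the siRNAs, against 8 in each; arrays left out gave 7 to 9 and 6 to 11. G2 and mitosis genes with siTCONS_00020760 turned upward without its Ad-LacZ array (adjusted p = 0.981), and the adjusted p over the arrays left out ran from 7.01e-06 to 0.981. Of the 36 differences in p53 response, 16 lay outside the random range, 11 with normexp and 11 with the authors' values. The mean agreement between infections was 0.374 and 0.534 with only probes well above background on all 8 arrays. Named genes kept direction in every alternative where they were called, and over all named genes 1105 of 1246 values were unchanged in call or within their spread, 133 lost the call, 3 gained it and 5 moved; with arrays left out, 551 of 782 were unchanged, 207 lost the call, 11 gained it and 13 moved. Over the called lists and their alternatives, 84 of 112 combinations kept the call, as did 90 of 104 with arrays left out, where 13 were lost and 1 reversed. The median over all genes under infection was -0.036, and -0.16 with quantile normalization, -0.12 with the authors' values and -0.11 with only probes well above background on all arrays. Signal over background limits the folds of 790 genes called higher and 64 called lower whose other group was not well above background. With 1 array left in an siRNA group, that array was taken to vary like the others. A slide block was not run, since there was 1 slide, and the alternatives for the targeted lincRNAs were not run, since no probe matched.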

Other observations

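The tests in this part, on lincRNA regions and their neighbours, were chosen only after the results were seen. Among the lincRNA regions higher with all 3 lincRNA siRNAs was a cluster on the forward strand of chromosome 3, where the region from 184997356 to 185033531 differed from siControl by 1.51, 1.67 and 1.82 with siTCONS_00004057, siTCONS_00020760 and siTCONS_00022563. The region on the forward strand of chromosome 12 from 79972444 to 79982744 differed by 2.39, 2.66 and 2.29. The reverse strand of the same stretch, counted as a further region, differed by 1.727, 1.936 and 1.805. Protein-coding genes of this group not named above included CYCS, the electron carrier cytochrome c (1.45, 1.31 and 1.39), the translation repressor EIF4EBP2 (1.61, 1.64 and 1.49), the coxsackievirus and adenovirus receptor CXADR (1.64, 1.01 and 1.28) and the magnesium transporter NIPA1 (1.74, 2.07 and 1.71). These items were chosen after their values were seen.

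LincRNA regions higher under Ad-p53 lay near genes higher under Ad-p53 more often than other regions did. Within 50000 bases of the nearest gene probe, 31 of 91 higher regions (34.1%) had a higher neighbour, against 129 of 728 other regions (17.7%), an odds ratio of 2.40 (1.44 to 3.93, two-sided Fisher's exact p = 0.00063, adjusted p = 0.0014 over 3 tests). Examples with the neighbour on the opposite strand, overlapping regions being joined, lay on chromosome 21 from 45228747 to 45238991 near AATBC (log2 difference 5.55) and on chromosome 9 from 119176804 to 119184004 near PAPPA, a metalloproteinase of insulin-like growth factor signalling (3.47). At the first, the reverse-strand region, on the neighbour's own strand, was also higher (at least 136-fold), so this example fits a longer transcript of the neighbour as well. The hypothesis tested was that shared local regulation may raise both, rather than unannotated parts of the neighbour's own transcript, which cannot be read from the opposite strand. With neighbours on the same strand the odds ratio was 3.01 (1.51 to 5.88, exact p = 0.00094), and on the opposite strand it was 1.79 (0.786 to 3.88, exact p = 0.14). Overlapping regions of either strand were joined and took the strand and call of the first in genome order. The opposite-strand set can therefore hold regions on the neighbour's own strand and is not a clean test. Its interval also includes 1 and values above 2, so these explanations cannot be told apart.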
